A study of Pseudomonas putida KT2440 with 4 samples.

How the data were processed

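Wild-type cells of 1 strain were sequenced in 4 libraries, 2 per form of lanthanum, as paired reads of total RNA on an Illumina instrument, per the labels' protocols. The deposited table gives raw counts per gene for each library, with 5671 gene identifiers and no normalization. It also gives the authors' mean of the raw counts per group, which is not scaled for library size and was not used, and the authors' log2 fold change of oxide over chloride with its p-value and q-value. HISAT2, StringTie 2.1.5 and DESeq 1.20.0 are named without roles, per the submitters' processing notes. The genome build, the annotation, the counting mode, the use of strand and any removal of ribosomal RNA are not given in the sources used here. Without strand, reads from a gene and an overlapping or antisense partner cannot be told apart, and genes with near-identical copies are uncertain. Recomputed with DESeq2 1.42.0, the log2 fold changes differed from the deposited ones by at most 2.2e-06, and the deposited q-values equal a Benjamini-Hochberg adjustment over all 5670 genes with a p-value (largest difference 1.8e-15).

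Of the 5671 identifiers, 0 matched the reference table of genes, which describes another assembly (LBNL_KT2440_1968) under other locus tags. The files do not pair identifiers with names, and none was inferred from the order of genes. Therefore the 25 gene lists fixed before the data were examined received 0 members and were not tested, and the restriction to protein-coding genes could not be made. Gene length, base composition and genomic positions were not analysed here. The rule for named genes, also fixed beforehand, asked first for 7 genes with ped symbols, given by locus tag. If none passed the adjusted threshold, it then asked for the 10 genes with the smallest unadjusted p in each direction. Last, it asked for list members. The first and last parts could not be applied, and of the second 2 identifiers per direction are printed and the others summarised.

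Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which removed 28 genes, and scaled by TMM. The quasi-likelihood test (glmQLFit, glmQLFTest) compared oxide with chloride with group as the only term, leaving 2 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg at 0.05. The SE of a fold change is its size divided by the square root of F. Log2 CPM used a prior count of 2. The coefficients of variation are square roots of edgeR's common dispersion within a pair. Alternatives were RLE scaling, no filter, a replicate block, each library left out, DESeq2, limma-voom (limma 3.58.1), and an added threshold of 1 on the log2 scale. Library quality weights, thinning to the total of oxide replicate 1, total count scaling and leaving out the 2 most abundant genes were chosen after seeing the data, as were the descriptions by library, abundance bin and neighbouring identifier. Same-numbered libraries did not deviate together from their group means (r = -0.019 over genes), and the labels do not say that a number marks a shared batch.

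The comparisons with no effect were simulated from negative binomial counts with the chloride means, the real library sizes and each group's own dispersion trend, in 20 draws (10 where models were refitted), with the same spread assumed for both oxide libraries. The tests were run beforehand on a single simulated data set per setting, with 200 changed genes. Its means came from all 4 libraries, and all genes of a group shared a single dispersion. With the chloride spread in both groups, edgeR recovered 100% of 4-fold and 100% of 16-fold changes over 5642 genes and called 7 unchanged genes. Identifiers are numbered in steps of 5 apart from 2 larger gaps, and consecutive means exactly 1 step of 5 apart. Longer distances were counted in genes tested. The depth ran from 5866350 to 50965705 counts per library, so that 3 counts, the floor set by counting error alone, correspond to 0.418 TMM-scaled CPM in oxide replicate 1 and 0.062 in oxide replicate 2. Reads carry no molecular identifiers, as far as the labels say, so counting error understates the error.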

Results

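Pseudomonas putida KT2440, a soil bacterium that is widely used in the laboratory, was grown on ethanol with lanthanum given as the soluble chloride or as the poorly soluble oxide. Lanthanides serve as the metal cofactor of an alcohol dehydrogenase in this species, and the series asks how the transcriptome differs between the 2 forms of the metal. RNA sequencing was done on 2 chloride libraries and 2 oxide libraries of wild-type cells. The sample titles write the formula of the oxide as La2Ox3, which differs from that in the growth protocol. Both were read as lanthanum oxide, and whether the titles mean another compound could not be checked. The medium held 2 µM of either compound, 35 mM ethanol and 5 µM iron sulfate. Nothing in the labels says that the libraries of a group came from separate cultures, so every p-value below measures only the spread between these libraries, which may be technical. The table lists 5671 genes by identifier without names, and genes are therefore described by identifier, abundance and position in the identifier series.

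The libraries differed in depth and in composition. Chloride replicate 1 held 46477849 counts, chloride replicate 2 held 38849512 and oxide replicate 2 held 50965705, whereas oxide replicate 1 held 5866350. A pair of unnamed genes took 40.4% and 41.1% of the counts in chloride replicates 1 and 2, 53.1% in oxide replicate 2 and 27.6% in oxide replicate 1. The gene of this pair with the higher total over all libraries accounted for 29.9% of oxide replicate 2 and 5.37% of oxide replicate 1, and the other gene for 23.1% and 22.3%. Oxide replicate 1 had 725 genes at 0, against 5, 31 and 9 in chloride replicates 1 and 2 and oxide replicate 2. When the other libraries were thinned at random to the total of oxide replicate 1, they had on average 32.9, 59.8 and 41.9 genes at 0 over 20 draws.

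The chloride libraries were close to each other and the oxide libraries were not. Over the 5643 genes tested, the Spearman correlation was 0.99 between the chloride libraries and 0.74 between the oxide libraries. Oxide replicate 2 correlated with the chloride libraries at 0.84 for either replicate, and oxide replicate 1 correlated with them at 0.66 and 0.65. The biological coefficient of variation was 19.7% within the chloride pair and 97.2% within the oxide pair. These correlations run across genes, which are not independent replicates. The chloride libraries differed by more than counting error (chi-square of 31.7 per degree of freedom), so the table does not hold the same library under both names. Technical libraries of a single culture would also exceed counting error.

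In the comparison of oxide with chloride, the 10 genes with the smallest p-values in each direction lay up to 186-fold apart between the groups. Those named here, chosen for the smallest p-values, were thereby also chosen for similar levels within each group. PP_RS18005 was at 2941 ± 104 CPM (counts scaled to library size by TMM) in chloride and 15.8 ± 2.58 CPM in oxide (SD, n = 2 libraries each), a log2 fold change of -7.54 ± 0.57 (SE). PP_RS07205 was at 219 ± 2.59 CPM in chloride and 3.64 ± 0.028 CPM in oxide, a log2 fold change of -5.91 ± 0.41. Its oxide level rests on 26 counts in replicate 1 and 177 in replicate 2, so the SD there understates even the counting error. In the other direction, PP_RS19500 was at 2.21 ± 0.89 CPM in chloride and 272 ± 40.7 CPM in oxide, a log2 fold change of 6.94 ± 0.58. PP_RS08545 was at 10.3 ± 0.73 CPM in chloride and 232 ± 5.92 CPM in oxide, a log2 fold change of 4.49 ± 0.39. None of these genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.134 for each), although the groups did not overlap. In the authors' deposited table they had q values of 1.63e-52, 2.28e-28, 1.15e-26 and 7.04e-18, in the order given here. All 4 genes passed an adjusted p of 0.05 in the same direction with DESeq2 and limma-voom, and in edgeR with either oxide library left out, where the chloride spread stands in for that of oxide. In edgeR they did not pass with the replicate block (adjusted p = 0.162) or with either chloride library left out (adjusted p from 0.783 to 0.999).

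**Figure D1:**
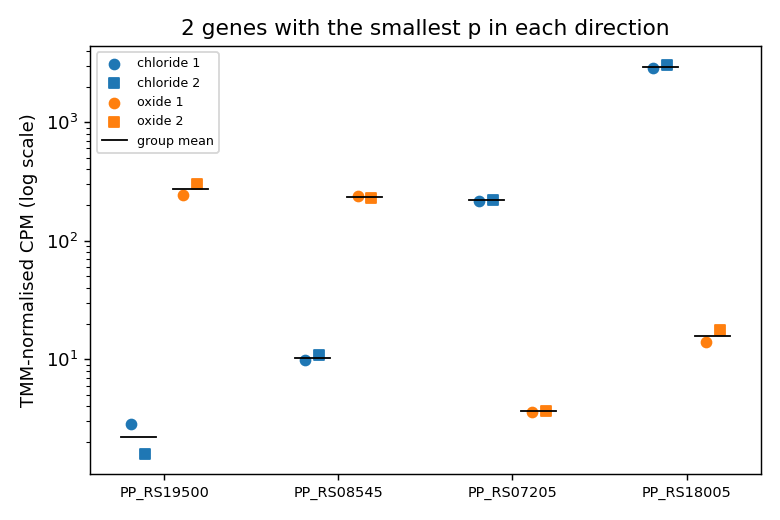
TMM-normalised CPM (log axis) of the 2 genes with the smallest p-values in each direction, in each of the 4 libraries. Circles are replicate 1, squares are replicate 2 and black lines are group means. PP_RS18005 lies at 2941 CPM in chloride and 15.8 CPM in oxide.

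The 10 genes with the smallest p-values among those higher in oxide had fold changes from 11.6 to 122. Their group means lay between 2.21 and 31.6 CPM in chloride and between 151 and 664 CPM in oxide. The 10 genes with the smallest p-values among those lower in oxide had fold changes from 10.4 to 186, with means from 90.3 to 3118 CPM in chloride and from 2.52 to 81.6 CPM in oxide. All 20 had q under 0.05 in the authors' deposited table, and none passed edgeR's test (adjusted p = 0.134). In each direction, 5 of the 10 had another member of their list, moving the same way, within 5 positions in the identifier series.

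Across the transcriptome, edgeR's quasi-likelihood test called 0 of 5643 genes higher and 0 lower at an adjusted p of 0.05. At an unadjusted p under 0.05, 547 genes were higher and 464 were lower in oxide, together 17.9% of the genes tested. The authors' deposited table holds 764 genes with q under 0.05, of which 428 were higher and 336 were lower in oxide. According to that table, the median log2 fold change was 2.75 for the genes that were higher and -2.24 for those that were lower. The fitted change between the groups was at least 2-fold in every one of the 764. Of these genes, 725 had an unadjusted p under 0.05 in edgeR. In 732 of the 764 both oxide libraries lay beyond both chloride libraries in the called direction, and in 721 by at least 2-fold. The selection of the calls on these same libraries favours both counts. Of all genes tested, 58.8% had groups that did not overlap in either direction, where chance gives 33.3% if all libraries vary alike, and simulations with no effect and each group's own spread gave 44.2% on average and at most 46.2%. Recomputed with DESeq2, the counts gave 804 calls (453 higher, 351 lower), and limma-voom gave 90 (54 higher, 36 lower). The DESeq2 calls shared 761 genes with the authors' 764. The recomputation left 661 genes without an adjusted p, whereas the deposited q-values were adjusted over 5670 genes, so the adjustment covered different sets. Without oxide replicate 1 edgeR called 2876 genes and without oxide replicate 2 it called 4083, each time with the chloride spread standing in for that of oxide. In a single simulated data set, each group had its own spread, which all its genes shared and real genes need not share. There, 0% of 4-fold and 0% of 16-fold changes were recovered by edgeR and likewise by limma-voom. DESeq2 recovered 20% and 74% and also called 60 unchanged genes, where edgeR and limma-voom called 0.

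Taken one at a time, the oxide libraries departed from chloride in the same direction for most genes in which both departed. Oxide replicate 1 was at least 2-fold above both chloride libraries in 1372 genes and at least 2-fold below both in 2077. Oxide replicate 2 was above in 970 genes and below in 892. Both oxide libraries were above in 515 genes, where independent lists of these sizes would share 236. Both were below in 642 genes, where independent lists would share 328. Which direction held more genes depended on the scaling, since total count scaling gave 606 above and 557 below. They departed in opposite directions in 153 genes, so that 88.3% of the genes in which both departed went the same way. The oxide libraries were set against the same chloride libraries, which by itself makes them alike. In 20 simulations with no effect of the oxide, the shared controls and the spread of each group gave 167 genes above in both, 478 below in both, and 56.1% in the same direction.

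The difference between each oxide library and the mean chloride library correlated at r = 0.41 across genes, with a covariance of 1.62 against 0.26 in the simulations without effect. When each oxide library was set against a different chloride library, so that none was shared, r was 0.37 and 0.39 for the 2 ways of doing so, with covariances of 1.53 and 1.56 against 0.20 and 0.21 in the simulations. Each oxide library then had a single control.

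**Figure D2:**
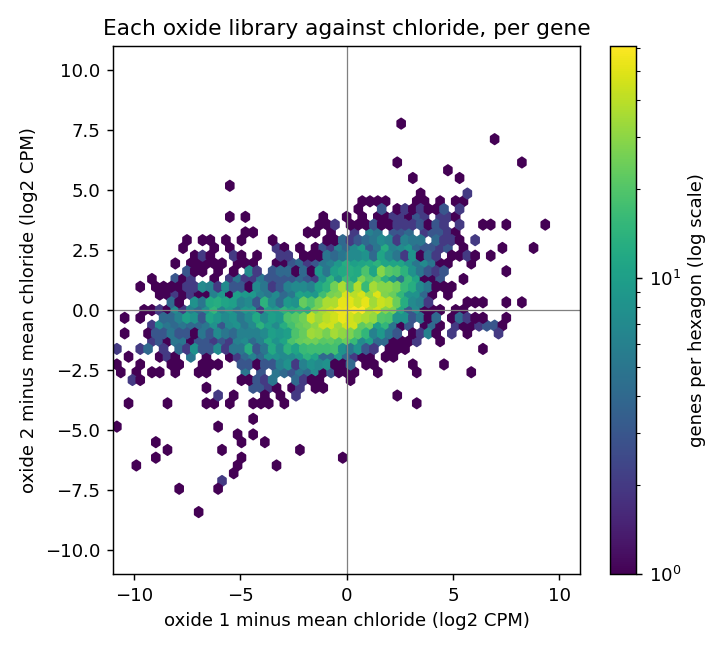
Log2 CPM of oxide replicate 1 (x axis) and oxide replicate 2 (y axis) minus the mean of the chloride libraries, for 5643 genes. Colour gives the number of genes per hexagon on a log scale. The points spread further along the x axis than along the y axis, and r is 0.41.

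Most of the genes that were abundant with chloride had lower values in each oxide library. Genes were ranked by CPM in chloride replicate 1, divided into 10 equal bins and measured against chloride replicate 2, so that the ranking and the reference did not share a library. In the most abundant bin (565 genes, median 415 CPM) the median log2 difference was -1.56 in oxide replicate 1 and -1.03 in oxide replicate 2, against 0.07 between the chloride libraries. In that bin, 80.9% of the genes were lower in oxide replicate 1 and 81.6% in oxide replicate 2. The next bin had medians of -0.97 and -0.51. In 20 simulations with no effect and the spread of each group, the most abundant bin had medians of -0.013 and 0.092. With the ranking reversed, in the most abundant bin by oxide replicate 2, the chloride libraries lay at -0.16 and -0.14 relative to oxide replicate 2, which also set the ranking. Against oxide replicate 1, which did not, they lay at 0.46 and 0.48, and oxide replicate 1 itself lay at -0.69 relative to oxide replicate 2. Of the genes in the 2 most abundant bins, 359 were at least 2-fold lower and 22 at least 2-fold higher in both oxide libraries. In the 5 least abundant bins the split was the other way, with 124 lower and 346 higher. The simulations gave 47.2 lower and 27.9 higher in the 2 most abundant bins, and 343 lower and 93.6 higher in the 5 least abundant. Leaving the dominant pair of genes aside, the most abundant bin held 75.3% and 76.8% of the remaining counts in chloride replicates 1 and 2, 55.3% in oxide replicate 1 and 59.1% in oxide replicate 2. These splits kept their direction under 3 scalings (TMM, RLE and total count). The median log2 fold change of all genes was 0.02 with TMM, -0.01 with RLE and 0.23 with total count scaling.

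**Figure D3:**
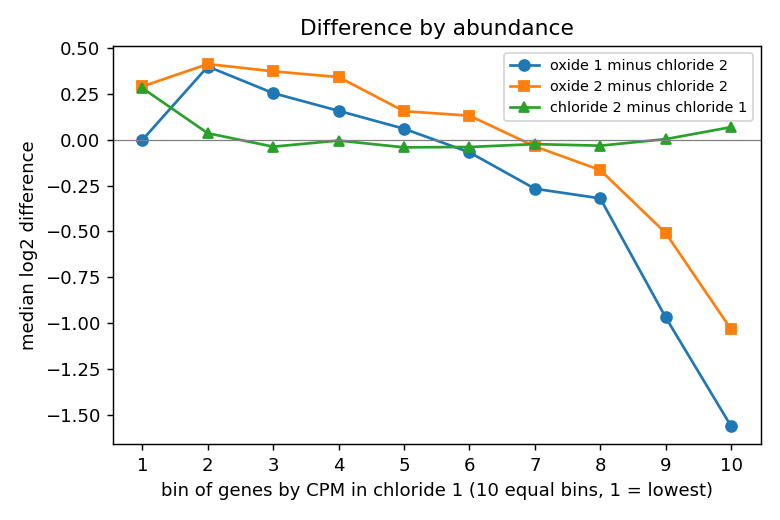
Median log2 difference (y axis) in 10 equal bins of genes ranked by CPM in chloride replicate 1 (x axis, 1 is the lowest). Circles and squares are oxide replicates 1 and 2 minus chloride replicate 2, and triangles are chloride replicate 2 minus chloride replicate 1. In the most abundant bin the oxide libraries lie at -1.56 and -1.03 and the chloride pair at 0.07.

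Genes with consecutive identifiers differed together. Between genes 1 position apart in the identifier series, the difference from mean chloride correlated at r = 0.52 in oxide replicate 2 and at r = 0.20 in oxide replicate 1. The difference between the chloride libraries correlated at r = 0.053, and the highest value in 1000 shuffles of the gene order was 0.041 for oxide replicate 1 and 0.038 for oxide replicate 2. At 5 positions the correlations were 0.066 and 0.055 for oxide replicates 2 and 1. Of the 1157 genes at least 2-fold away from both chloride libraries in both oxide libraries, 316 (27.3%) lay in 75 runs of at least 3 consecutive identifiers with 1 direction. Shuffled orders gave 11 runs on average and at most 20. Of these runs, 39 with 161 genes were higher in oxide and 36 with 155 genes were lower, and the longest held 8 and 13 genes, where the longest run in any shuffled order held 9. The 764 calls of the authors' deposited table formed 55 runs with 209 genes, against at most 10 runs in 1000 shuffles. All these shuffles ran over all genes and did not keep neighbours of similar abundance together.

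**Figure D4:**
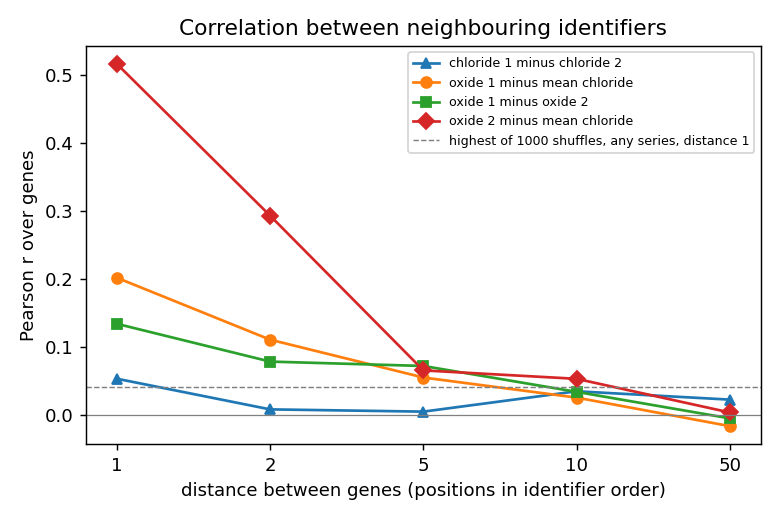
Pearson correlation over genes (y axis) between the differences of genes that lie 1, 2, 5, 10 or 50 positions apart in the identifier series (x axis, not to scale), for 4 differences between libraries. At distance 1, r is 0.52 for oxide replicate 2, 0.20 for oxide replicate 1 and 0.053 for the chloride pair.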

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

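The count of 0 edgeR calls held with RLE scaling, no filter, thinning, total count scaling and the 2 most abundant genes left out (the last 3 chosen after seeing the data). The added fold threshold can only remove calls, so its 0 was fixed beforehand. In the single data set simulated with each group's own spread, shared by its genes, edgeR recovered 0% of 4-fold and 0% of 16-fold changes. A steady 0 therefore does not show that genes were unchanged. The replicate block also gave 0 calls, and the samples share only a number. DESeq2 gave 804 calls (453 higher, 351 lower) and limma-voom gave 90 (54 higher, 36 lower). Library quality weights, added later, gave 661 (394 higher, 267 lower), with weights of 0.247 and 0.265 for the oxide libraries and 3.96 and 3.85 for the chloride libraries. With 2 libraries per group, the weights within a pair must come out nearly equal, so they cannot show which oxide library is further off. With each library left out in turn, the calls ranged from 0 to 4083 (0 to 1670 higher, 0 to 2413 lower). Leaving out a chloride library gave 0, leaving out oxide replicate 1 gave 2876 (1426 higher, 1450 lower) and leaving out oxide replicate 2 gave 4083. A lone oxide library is then assumed to vary like the chloride pair, whose coefficient of variation was 19.7% against 97.2% in the oxide pair, so these 2 counts are not evidence of replicated change. With a library left out, genes had to be 2-fold beyond each remaining chloride library in each remaining oxide library. Those above then ranged from 616 to 1372 and those below from 714 to 2077. The highest came without oxide replicate 2, since only 1 oxide library then has to depart. Without oxide replicate 1 they were 970 and 892. Without chloride replicate 2 they were 616 and 714, and without chloride replicate 1 they were 697 and 747. Only 1 chloride library then has to be passed, so these exceed the 515 and 642 of all libraries. The most abundant bin and the neighbour correlation kept their direction under all alternatives run. The log2 fold changes of the 4 printed genes kept their direction in all 13 alternatives, 5 of which brought each past the threshold. The gene list tests and the protein-coding restriction were not run because 0 identifiers could be named. The cause of the difference between tools was not tested beyond the simulations. Depth limits oxide replicate 1, where the median gene had 121 counts against 974 in oxide replicate 2.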

Other observations

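The tests of explanations in this part were chosen after the results were seen, whereas the calls by DESeq2 and those with 1 oxide library left out were planned.

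When each oxide library was tested alone against the chloride pair, 760 genes were called higher and 1115 lower with both libraries, among 5654 genes. Independent lists of the same sizes would share 420 and 619, and simulations without effect gave 535 and 668. Oxide replicate 1 higher with oxide replicate 2 lower was called for 118 genes and the reverse for 301, against 512 and 581 in the simulations. The simulations hold the shared chloride libraries and the same fits with 1 oxide library, and the independent lists hold neither. The simulations assume the same spread in both oxide libraries.

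Genes with consecutive identifiers differed together in both oxide libraries. A candidate explanation is that neighbouring genes are transcribed together, as in bacterial operons. The correlation for oxide replicate 2 fell from 0.52 at 1 position to 0.29 at 2, 0.066 at 5, 0.053 at 10 and 0.0036 at 50 positions. Only the last was below the highest of 1000 shuffles (0.038). Joint transcription of adjacent genes may account for the steep fall over the first positions, while the value at 10 positions is left unexplained. The shuffles ran over all genes and did not keep abundance, on which the oxide difference depended. Neighbours of similar abundance could therefore also correlate, and the shuffles cannot tell the 2 apart. The hypothesis was not tested against reads that run across gene ends.

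Oxide replicate 1 had 725 genes at 0. Lower read depth is argued against as the whole cause, since no other library thinned to its total had more than 59.8 genes at 0 on average. A library made from few RNA molecules is a candidate explanation. Among genes for which oxide replicate 2 leads to an expected 10 to 30 counts, 29.1% were at 0. Among those expected at 100 to 300 it was 4.15%, at 300 to 1000 it was 0.756%, and among the 501 genes expected at 1000 or more it was 0. Any loss that falls with abundance would give such a gradient, so these shares cannot single out few molecules. Genes that were silent in that culture remain possible, and no biological explanation was tested.

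The oxide libraries also differed among the most abundant genes, where few molecules matter least. In the most abundant of 10 bins, here ranked by the mean of all 4 libraries, their median absolute log2 difference was 0.96 (bootstrap SD 0.046), against 0.084 for the chloride pair, which argues against few molecules as the whole cause. An exchange of oxide replicate 1 with a chloride library is argued against by their Spearman correlation in that bin, which was at most 0.13, compared with 0.48 between the oxide libraries. Oxide replicate 2 correlated at 0.43 with chloride replicate 1 there, so 0.48 is not a likeness particular to the oxide pair. Noise that is independent from gene to gene would give no correlation between consecutive identifiers above the shuffles. Over all genes, the difference between the oxide libraries correlated between them at r = 0.134, above the highest of 1000 shuffles (0.041). The chloride pair, at 0.053, also lay above its own highest shuffle (0.037). The shuffles over all genes did not keep abundance, so these correlations may follow the abundance of neighbours. They therefore cannot decide whether independent noise was the whole cause. Within the bin alone, independent noise cannot be told apart from a shared shift of neighbours, because r over 225 pairs was 0.19 and the highest of 1000 shuffles was 0.23. A different state of the 2 oxide cultures, degraded RNA, and a single wrong label from outside the series remain open and could not be tested without gene names or lengths.

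DESeq2 called 804 genes where edgeR called 0. Unequal spread of the groups with no effect gave DESeq2 68.2 calls on average and at most 101 in 10 simulated data sets, and gave edgeR 0. This may account for part of the 804, and because the simulated spread is an assumed profile with equal noise in both oxide libraries, it cannot be told apart how large that part is.

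The 2 compounds were given at the same 2 µM, and, if the titles and the protocol name the same oxide, a formula unit of it holds more lanthanum atoms than one of the chloride, so the form of the metal and its total amount differ together between the groups.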
